A study of Mus musculus with 6 samples.

How the data were processed

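Capture Hi-C was performed on mouse limb buds at E12.5. Per the labels' protocols, limbs were dissociated with trypsin, cells were fixed with paraformaldehyde and lysed, and adaptor-ligated DNA was hybridised to custom SureSelect probes, amplified before and after hybridisation, and sequenced in paired-end mode with each sample on its own lane. The labels place 1 library in each of 6 genotypes: WT, deltaBor, Dup-S, Dup-L, Dup-C and Dup-LdeltaBor. The number of animals pooled and the zygosity of the mutants are not given in the sources used here. Samples other than these mouse libraries were not analysed here.

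Reads were mapped with Bowtie2 2.2.6 to mm9, per the submitters' processing notes. The names of the deposited files mark a mapping quality of 30 and bins of 10 kb. How read pairs were filtered, whether duplicates were removed, and the tool used for matrix balancing are not given in the sources used here. The authors deposited, for each library, a map of raw contact counts per pair of bins. They also deposited a signal map of the same library after KR (Knight-Ruiz) balancing, in which bins have equal sums: the coefficient of variation of the bin sums was 33.4% (WT) to 68.8% (Dup-LdeltaBor) in the raw maps and at most 3.12e-06% in the KR maps, leaving out empty bins. In addition, 7 comparison maps were deposited: 2 hold log2 ratios made by the authors from scaled raw maps, and 5 hold differences made by the authors from scaled raw maps. On the files' values, each deposited difference map was the mutant's raw map times a factor minus the control's raw map times another. How those factors were chosen is not given in the sources used here. The Dup-C and Dup-S maps give positions as offsets, and were placed on the same 587 bins. Their log contact sums per bin correlated most highly with those of WT at a shift of 0 (0.838 and 0.960, against at most 0.564 and 0.579 at shifts of 1 to 5 bins).

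Raw counts were the main values, with contacts of bins under 2 bins apart left out. The altered segment of each mutant was the run of bins whose mean log2 ratio of contact sums to WT (pseudocount 0.5, centred on the median) differed most from the rest, by a circular binary segmentation statistic. The insulation score was the mean contact count in a 500 kb diamond at each bin, log2 over the mean of all bins. Domain ends were local minima with a prominence of at least 0.3 log2, and the boundary was the WT minimum nearest to the bin lost in deltaBor. P and Q are the duplicated stretches on the centromeric and telomeric sides of the boundary bin, and the rests are the unduplicated parts of the domains.

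Each mutant was compared with WT, and Dup-LdeltaBor with Dup-L. A fold is the ratio of contact counts in a region after scaling on contacts with both bins outside, and on the same side of, the altered segment. For deltaBor, scaling used contacts on the same side of the boundary without the lost bin. Folds carry an exact (Clopper-Pearson) 95% binomial interval conditional on the 2 counts, and the error of the scaling factor is not part of it. Region folds were set beside folds of control blocks of 100 kb by 100 kb outside the altered segment at distances within 100 kb, and block medians beside 10000 distance-matched draws; these are descriptions of the libraries, not tests of the genotypes. Blocks within the domains of deltaBor, and some of the rest of the domain in Dup-S, are among their own controls. The scaling contacts left a median control block fold of 0.987 in deltaBor, 1.03 in Dup-S, 1.02 in Dup-L, 0.980 in Dup-C and 0.994 in Dup-LdeltaBor over Dup-L. A count of 0 was read as up to 3 counts. Depth ran from 4144258 contacts in Dup-C to 8965219 in Dup-LdeltaBor.

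The regions described, the tests and the alternatives were chosen before the data were examined, except where said otherwise. Named regions were the altered segments, the domains, P, Q, their rests and the junction corners, and per comparison the 5 blocks with the largest gain and the 5 with the largest loss among those with at least 50 counts in both libraries. Contacts of single gene starts were planned only with an annotation on mm9, and were not run. The gene table used here is on GRCm38, so it gave only names and their order, and no position. Genes are named as background.

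The alternatives were KR-normalised values, scaling to the library total, leaving out contacts under 10 bins apart, leaving out 10 bins of low coverage, equal weight for each distance, a 200 kb diamond, a prominence of 0.15, junction corners of 50 kb and 200 kb, and other ways of finding segments. Alternatives added after seeing the data were a telomeric-side domain taken to the next minimum, 2 more bins left out on each side of the lost bin, the lost bin left out of the WT share between domains, deltaBor scaled on contacts outside the Dup-L segment, and the piece duplicated only in Dup-C.

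The procedures were tested on simulated data. Over 70 simulated maps at the depths of deltaBor, Dup-S, Dup-L and Dup-C, the segment was found exactly in 70, the interval held the true fold in 65, and the largest error of a fold was 0.800%. Among simulated blocks at the depth of Dup-C, 44 of 50 with a true fold of 0.8 and 41 of 50 with a true fold of 1.25 had an interval on the correct side of 1, as had all 49 with a true fold of 0.5 and all 50 with a true fold of 2. These simulations drew counts without spread beyond counting error. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.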

Results

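Capture Hi-C was used to count contacts between pieces of chromatin at the Sox9/Kcnj locus of mouse chromosome 11. In this assay, DNA ends that lie close together in the nucleus are ligated, fragments from a chosen region are enriched with probes, and each ligated pair is counted as a contact between 2 bins. The locus holds Sox9, a transcription factor of cartilage and gonad development, and the potassium channel genes Kcnj2 and Kcnj16. In the GRCm38 gene table, the protein-coding genes run in the order Map2k6, Kcnj16, Kcnj2, Gm11677 and Sox9. All samples were limb buds at E12.5, with 1 library for each of 6 genotypes. WT was the control. The deltaBor mice lack a domain boundary, Dup-S, Dup-L and Dup-C carry duplications of different extents, and Dup-LdeltaBor carries the duplication of Dup-L without the boundary. The maps covered 109010001 to 114880000 in mm9, in 587 bins of 10 kb.

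Total contacts were 7051882 in WT, 6337918 in deltaBor, 5280553 in Dup-S, 8244295 in Dup-L, 4144258 in Dup-C and 8965219 in Dup-LdeltaBor. Between 83.8% (Dup-C) and 96.1% (WT) of the 172578 possible bin pairs held a contact. No genotype had replicates, so no test across genotypes was possible and no p-value is given. The 95% intervals are exact binomial (Clopper-Pearson) intervals that treat contacts as independent, and cover counting error only. Whether duplicates of amplified reads were removed is not given, and any left would make the intervals too narrow. As a further yardstick, each region's folds were set beside those of blocks of 100 kb by 100 kb outside the altered segment at matched distances.

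The first question was where each genome differed from WT, which also checks the genotype labels. In deltaBor the altered segment was 1 bin, 111390001 to 111400000, which held 24790 contacts in WT and 0 in deltaBor, a count that allows up to 0.015% of the WT level. The bins on either side kept 19.4% and 58.2% of their WT contacts, relative to the median bin of the Dup-L segment. Dup-S carried a gain of 420 kb from 111750001 to 112170000, with a median bin ratio of 1.57 over the bins outside it. Dup-L carried a gain of 1560 kb from 110960001 to 112520000 with a ratio of 1.78. The gain in Dup-C reached from 110770001 to the same end, 1750 kb in all, with a ratio of 2.05. In the published description of these mice, Dup-C includes Kcnj2 and Kcnj16 and Dup-L ends before Kcnj2. Dup-LdeltaBor had the same gained segment as Dup-L, at a higher ratio of 2.48, and a loss of 20 kb from 111380001 to 111400000 relative to Dup-L. The bin lost in deltaBor kept 2.84% of its Dup-L level there, relative to the median bin of the gained segment. The bins on either side kept 20.6% and 59.4%, close to the shares in deltaBor, so the 2 lengths do not show deletions of different extents. Thresholds on a running median gave 30 kb for the deltaBor loss.

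**Figure D1:**
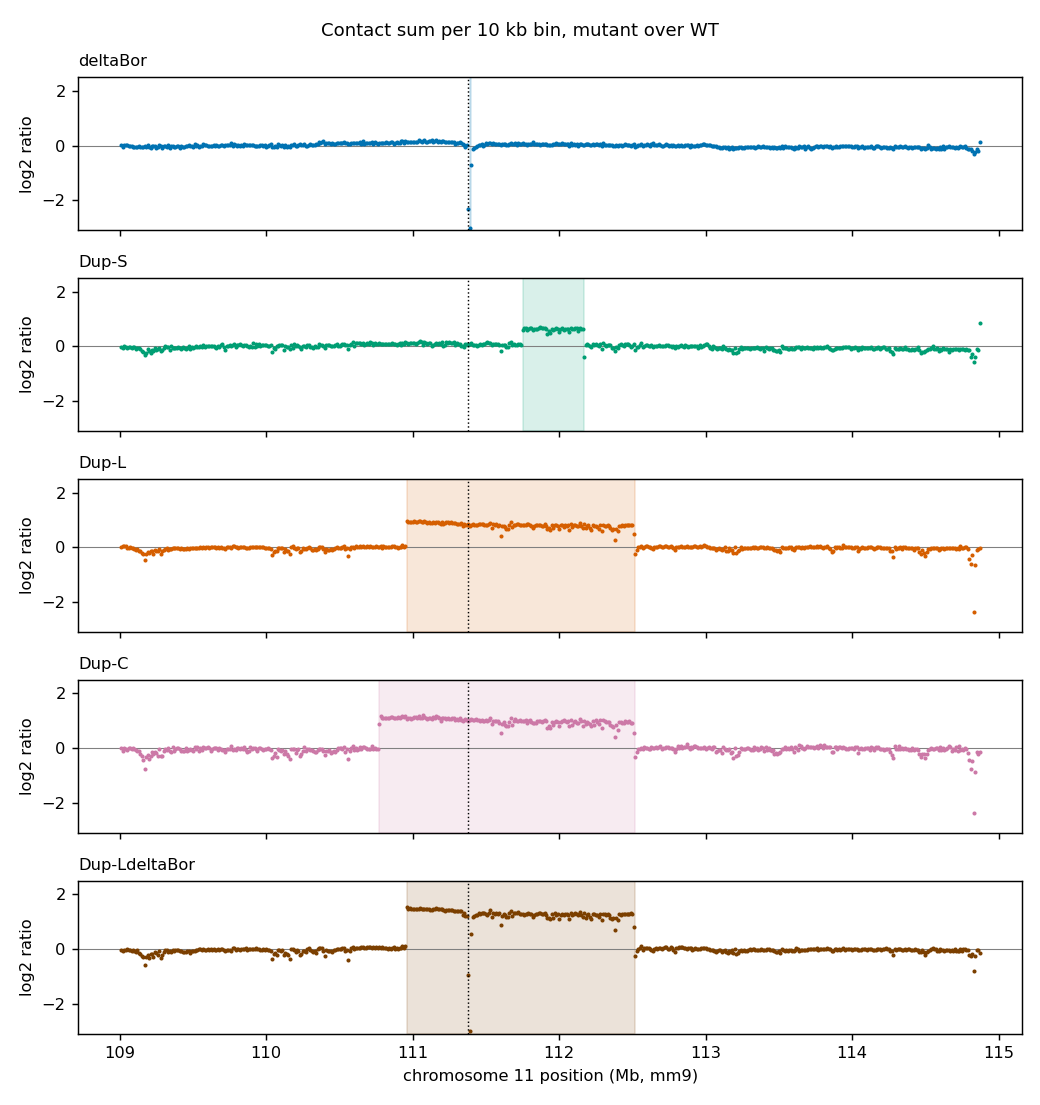
Log2 ratio of the contact sum of each 10 kb bin in each mutant over WT (y axis, empty bins drawn at the lower edge) along chromosome 11 in Mb of mm9 (x axis); shading marks the altered segment and the dotted line the WT boundary bin. The gains span 420 kb in Dup-S, 1560 kb in Dup-L and Dup-LdeltaBor and 1750 kb in Dup-C, with median ratios of 1.57, 1.78, 2.48 and 2.05.

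In WT, a boundary separated a centromeric-side domain, 110200001 to 111380000 (1180 kb), from a telomeric-side domain, 111390001 to 112650000 (1260 kb). The boundary bin, 111380001 to 111390000, had an insulation score of -1.46, the mean contact count across the bin on a log2 scale relative to all bins. Only 11.9% (95% interval 11.9 to 12.0) of the contacts of these domains joined one to the other. The telomeric-side domain ended at a shallow minimum of -0.08, and the next one, of -0.91, lay beyond 113030000. A 200 kb diamond in place of 500 kb moved the start of the centromeric-side domain to 110930001 and the share between domains to 7.69%. Kcnj2 and Kcnj16 are known to lie on the centromeric side of the boundary and Sox9 on the telomeric side; no gene position in mm9 was used here.

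Deleting the boundary addresses whether it keeps the domains apart. In deltaBor, contacts between the domains rose 1.65-fold (1.64 to 1.66), from 226164 in WT to 300838 before scaling. Their share of the contacts of both domains was 17.7%, against 11.7% in WT with the lost bin left out. All 132 blocks between the domains lay above every control block at their distance, with folds of 1.17 to 2.76. The 5 blocks with the largest gains joined chromatin on either side of the lost boundary and 4 of them involved 111410001 to 111510000, led by 111210001 to 111310000 with 111410001 to 111510000 at 2.76 (2.64 to 2.89). The centromeric-side rest outside the Dup-L segment and the telomeric-side rest, at the far ends of the domains, gained 1.48-fold (1.44 to 1.52) with each other. The 5 largest losses, 0.633 to 0.694, joined the telomeric-side domain to chromatin beyond it, and 4 of them involved 111410001 to 111510000. Contacts within the centromeric-side domain had a fold of 1.03 (1.03 to 1.03) and those within the telomeric-side domain a fold of 1.01 (1.00 to 1.01). These contacts also set the scale and supply the control blocks, so their folds are held near 1 and do not test for a change within the domains. Scaled on contacts outside the Dup-L segment instead, a choice made after seeing the data, the stretches of that segment had folds with themselves of 1.07 (1.06 to 1.07) on the centromeric side and 1.00 (0.998 to 1.00) on the telomeric side. The folds within both domains turned below 1 when scaled to the library total (0.923 and 0.903), with KR-normalised values (0.971 and 0.988) and with distances weighted equally (0.934 and 0.891).

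**Figure D2:**
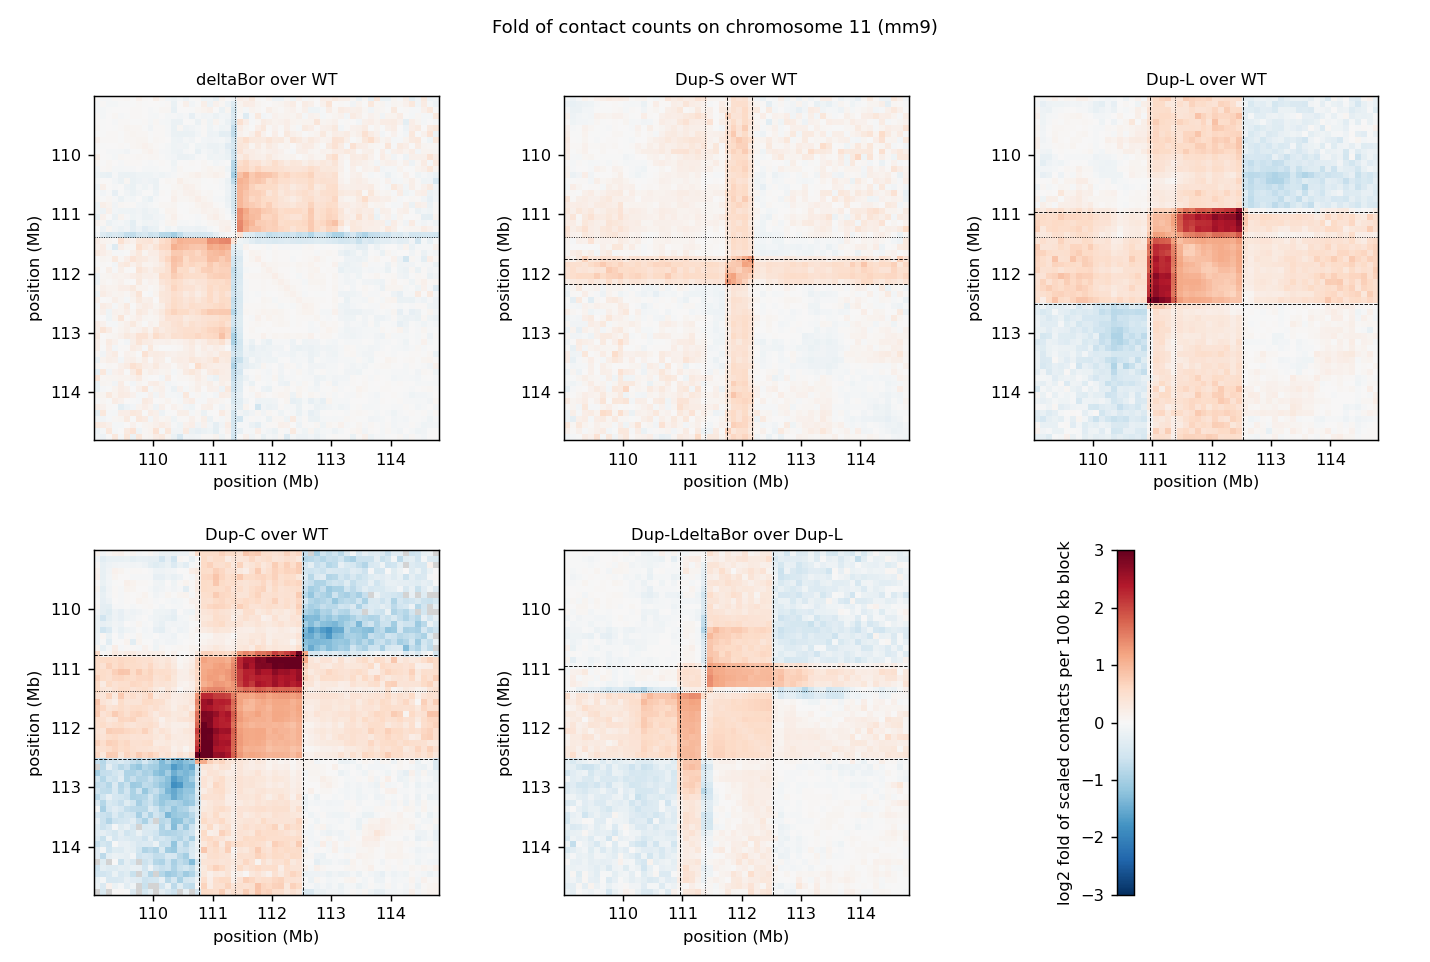
Log2 fold of scaled contact counts per block of 100 kb by 100 kb in 5 comparisons, with positions on chromosome 11 in Mb of mm9 on both axes; dashed lines mark the duplicated segment, dotted lines the WT boundary, grey blocks had under 50 counts in a library, and colours saturate at the ends of the scale. The highest blocks reach 2.76 in deltaBor, 2.52 in Dup-S, 8.03 in Dup-L and 17.2 in Dup-C over WT, and 2.68 in Dup-LdeltaBor over Dup-L.

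Dup-S, a duplication inside the telomeric-side domain, addresses what a gain of copies does when no boundary is included. The duplicated segment contacted itself 1.92 times as often as in WT (1.91 to 1.93), and all 6 of its blocks lay above every control block. With the rest of its own domain its contacts rose 1.33-fold (1.32 to 1.33), and 21 of 21 blocks lay above the controls. With the centromeric-side domain they rose 1.45-fold (1.44 to 1.47), and 31 of 33 blocks lay above the controls. The segment was chosen by its gain, with a median bin ratio of 1.57, and the control blocks lie outside it. Copy number alone can therefore raise these raw folds and block counts, which do not show more contacts per copy. The rest of the telomeric-side domain, which was not duplicated, had a fold of 1.01 (1.00 to 1.02) with the centromeric-side domain. There 4 of 77 blocks lay below all controls, of which 33 blocks were themselves a part, and the median block fold of 1.02 stood near the lowest draw (1.01). Scaling to the library total gave 0.917 for this region and KR-normalised values 0.978. Of the contacts of both domains, 11.5% joined one domain to the other. The 5 largest block gains, 1.91 to 2.52, lay within or across the ends of the duplicated segment. The 5 largest losses, 0.797 to 0.842, lay at separations of 3000 to 5300 kb, with 116 to 192 contacts each in Dup-S, and the intervals of 3 of them included 1. With KR-normalised values the segment's fold with itself was 1.06, and that with the rest of its domain was 0.995, below 1.

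Dup-L spans the boundary and addresses whether the repeat forms a domain of its own. Its duplicated segment consists of P, 420 kb on the centromeric side of the boundary bin, and Q, 1130 kb on the telomeric side. P contacted Q 4.70 times as often as in WT (4.66 to 4.73), with 365344 contacts against 82664 before scaling. Within the pieces the folds were lower, at 1.96 (1.95 to 1.98) for P with itself and 1.88 (1.88 to 1.89) for Q with itself. All 33 blocks of P with Q lay above every control block, at 3.41 to 8.03. The 5 largest gains joined P to Q, led by 111010001 to 111110000 with 112410001 to 112510000 at 8.03 (7.54 to 8.56), 1400 kb apart on the reference. Among them, the block of 110910001 to 111010000 with 112410001 to 112510000 reaches past the centromeric end of P. With KR-normalised values the fold of P with Q was 2.21, and P with itself (0.884) and Q with itself (0.956) fell below 1.

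Contacts with the unduplicated flanks changed less in Dup-L. P rose by 0.38 on the log2 scale (1.26- to 1.34-fold) with the telomeric-side rest, 130 kb long, and Q rose 1.34-fold (1.33 to 1.35) with the centromeric-side rest, 760 kb long, where 71 of 76 blocks lay above the controls. P with the centromeric-side rest of its own domain had a fold of 1.17 (1.17 to 1.18). The outer flanks lost contacts with each other, at 0.619 of WT (0.601 to 0.637), and the 5 largest block losses, 0.527 to 0.540, joined the centromeric-side rest to chromatin beyond the telomeric-side domain. With KR-normalised values P with the telomeric-side rest (0.920), Q with the centromeric-side rest (0.973) and P with the centromeric-side rest (0.804) turned below 1; scaling to the library total turned only the last of these (0.946).

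Dup-C extends the duplication further to the centromeric side. P was 610 kb long and Q 1130 kb, and P contacted Q 5.75 times as often as in WT (5.71 to 5.79), with all 55 blocks above every control block at 4.08 to 17.2. P with itself had a fold of 2.30 (2.29 to 2.31) and Q with itself 2.11 (2.10 to 2.11). The largest gain joined 110810001 to 110910000 with 112410001 to 112510000 at 17.2 (16.2 to 18.2), and 4 of the 5 largest gains had this first interval. P rose 1.23-fold (1.19 to 1.27) with the telomeric-side rest and Q 1.22-fold (1.21 to 1.23) with the centromeric-side rest. Contacts of P with the centromeric-side rest had a fold of 1.16 (1.15 to 1.17), and the outer flanks fell to 0.363 of WT (0.343 to 0.385). The 5 largest losses, 0.277 to 0.346, again joined the centromeric-side rest to chromatin beyond the telomeric-side domain or across its end. With KR-normalised values P with Q was 2.36, P with itself 0.916 and Q with itself 0.958. The 3 raw flank folds above 1 contain the copy number of the duplicated segment, whose bins had a median ratio of 2.05. They turned below 1 both with KR-normalised values and with scaling to the library total, at 0.840 and 0.841 for P with the telomeric-side rest.

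**Figure D3:**
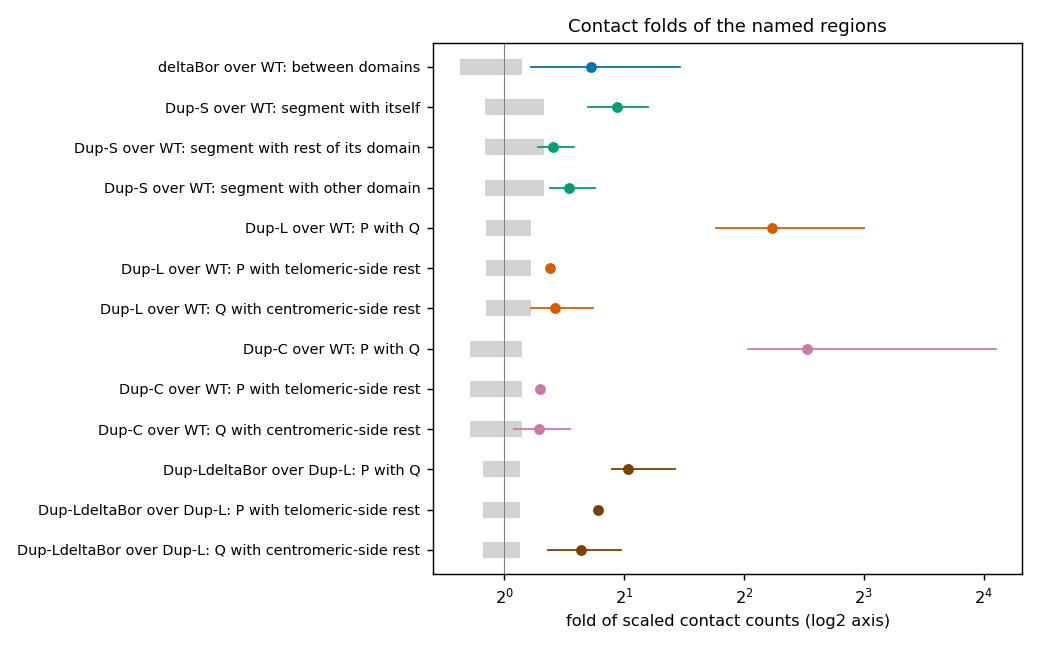
Fold of scaled contact counts of the main regions, without the junction corners, on a log2 axis (points) for the 5 comparisons. Lines give the range over 100 kb blocks, where full blocks exist, and grey bars the central 95% of control block folds. Among these regions P with Q stands highest, at 4.70 in Dup-L and 5.75 in Dup-C over WT and 2.04 in Dup-LdeltaBor over Dup-L.

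Removing the boundary from the duplication addresses how far it separates P from Q inside the repeat. In Dup-LdeltaBor, contacts of P with Q rose a further 2.04-fold (2.03 to 2.05) over Dup-L, with all 33 blocks above every control block at 1.86 to 2.68. The 5 largest gains joined P to Q, 4 of them with 111410001 to 111510000, led by 111110001 to 111210000 with 111410001 to 111510000 at 2.68 (2.61 to 2.74). Among them, the block of 110910001 to 111010000 with 111410001 to 111510000 reaches past the centromeric end of P. Dup-LdeltaBor also had more contacts inside P (1.37, 1.36 to 1.38) and inside Q (1.42, 1.41 to 1.42), which do not cross the boundary. Same-bin contacts inside the segment were 1.37 times those of Dup-L, as a median over bins relative to the median bin outside it. That is not the scale of the region folds. Against WT, with the lost bin left out, P with Q reached 9.71 (9.64 to 9.78) in Dup-LdeltaBor, 4.76 in Dup-L and 1.78 in deltaBor. P rose 1.72-fold over Dup-L (1.68 to 1.77) with the telomeric-side rest and Q 1.56-fold (1.55 to 1.57) with the centromeric-side rest, where 76 of 76 blocks lay above the controls. P with the centromeric-side rest of its own domain had a fold of 0.999 (0.993 to 1.00), while its median block fold of 1.05 lay above the highest distance-matched draw (1.04). The fold of that region was 0.822 with KR-normalised values, 0.865 when scaled to the library total and 0.957 with distances weighted equally. The outer flanks fell to 0.749 (0.722 to 0.776), and the 5 largest losses, 0.610 to 0.645, joined chromatin on opposite sides of the duplication. With KR-normalised values P with Q was 1.37, while P with itself (0.896) and Q with itself (0.961) fell below 1.

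The first and last 100 kb of each duplicated segment, far apart on the reference, meet at the junction of a head-to-tail repeat. In Dup-S, where they are 320 kb apart, their contacts rose 3.11-fold (3.03 to 3.19) over WT. The rise was 10.9-fold (10.2 to 11.5) in Dup-L, 20.3-fold (19.2 to 21.6) in Dup-C and 21.1-fold (19.9 to 22.3) in Dup-LdeltaBor. Set against the contacts of adjacent 100 kb stretches in WT, the scaled junction contacts were 1.15 in Dup-S, 0.530 in Dup-L, 1.06 in Dup-C and 1.03 in Dup-LdeltaBor. Direct contacts of the corners were not subtracted. In WT these already numbered 9114 for Dup-S, against 1211 for Dup-L and Dup-LdeltaBor and 1290 for Dup-C. KR-normalised values lowered these folds to 1.69, 5.01, 9.14 and 6.41, and for Dup-C 50 kb corners gave 34.1 and 200 kb corners 13.4.

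Insulation at the WT boundary bin was -1.46 in WT and -1.43 in Dup-S. The score there was higher in deltaBor at -0.49, in Dup-L at -0.09, in Dup-C at 0.23 and in Dup-LdeltaBor at 0.69. Relative to the centromeric-side domain's outer end in the same library, the boundary stood at -0.12 (-0.14 to -0.10) in WT and at -0.00 (-0.02 to 0.02) in Dup-S. The difference was 0.95 (0.94 to 0.97) in deltaBor, 1.69 (1.68 to 1.70) in Dup-L, 2.21 (2.19 to 2.23) in Dup-C and 2.84 (2.83 to 2.85) in Dup-LdeltaBor. In Dup-S the minimum stayed at the boundary bin. In Dup-L and Dup-C a minimum remained within 10 kb of it, with a prominence of 0.37 and 0.41 log2 against 2.26 in WT. With a 200 kb diamond and KR-normalised values the minimum lay at the boundary bin, at -0.98 and -0.91 against -1.60 in WT. The nearest minimum in deltaBor lay 120 kb to the telomeric side at 111500001, with a score of -0.70 against -0.72 in WT at that bin. A 200 kb diamond gave -0.89 there against -0.60 in WT (-0.84 against -0.67 with KR-normalised values), while KR-normalised values with 500 kb placed the minimum at 111490001, at -0.69 against -0.82. In Dup-LdeltaBor there was none within 200 kb of the boundary, and a 200 kb diamond placed one at 111500001. Raw scores contain the copy number of the duplicated bins. Where a duplication spans the boundary, contacts of P with Q through a head-to-tail junction also fall in the diamond. A higher score there does not by itself show a weaker boundary. With KR-normalised values the differences were 0.56 in deltaBor, 0.25 in Dup-L, 0.43 in Dup-C, 0.84 in Dup-LdeltaBor, -0.47 in WT and -0.51 in Dup-S.

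**Figure D4:**
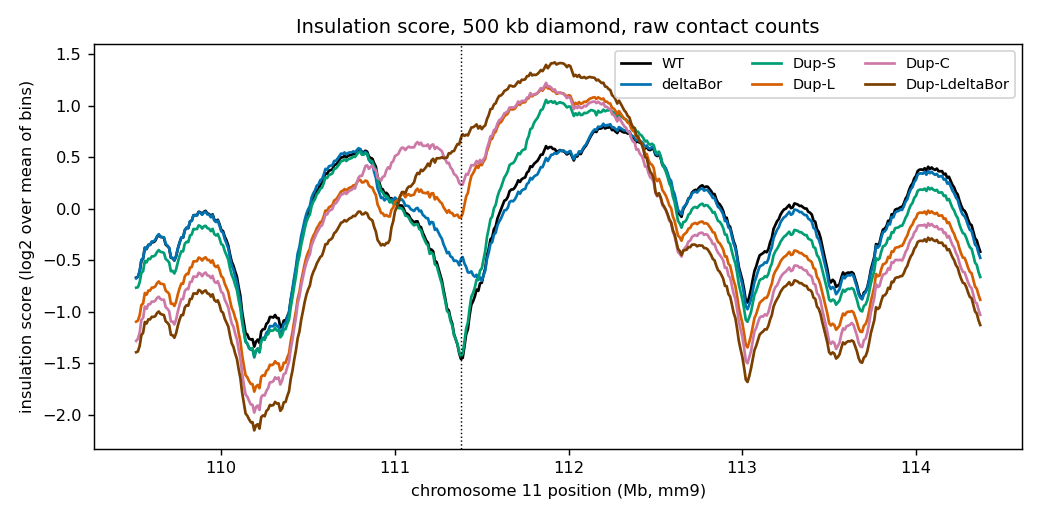
Insulation score (y axis, log2 mean contact count in a 500 kb diamond over the mean of all bins) along chromosome 11 in Mb of mm9 (x axis) for the 6 libraries, with the WT boundary bin as a dotted line. At that bin WT and Dup-S have -1.46 and -1.43, deltaBor -0.49, Dup-L -0.09, Dup-C 0.23 and Dup-LdeltaBor 0.69.

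In the authors' deposited difference maps, 100% of the P with Q bin pairs were above 0 in Dup-L minus WT, 99.99% in Dup-C minus WT and 99.9% in Dup-LdeltaBor minus Dup-L, and 80.0% of the pairs between the domains in deltaBor minus WT. In Dup-S minus WT, the authors' deposited map was above 0 in 100% of the pairs within the duplicated segment. The authors' deposited log2 map of Dup-LdeltaBor over Dup-L had a median of 0.86 in P with Q, and that of WT over deltaBor a median of -0.53 between the domains.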

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

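The tests in this part were chosen after the result was seen, except those on same-bin contacts and on the decay of contacts from the junction; in the decay test, the rule that all forms must give the same answer and the slopes over the shorter WT domain were added after the first slopes had been seen.

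Contacts between the outer flanks had folds on opposite sides of 1 in the comparisons that involve the deletion: 1.48 in deltaBor over WT and 0.749 in Dup-LdeltaBor over Dup-L. Each background has 1 library, and the difference between the effects was not tested. The bin lost in deltaBor, left out of the region folds of these comparisons, held 1606 contacts in Dup-LdeltaBor, above the 3 that a count of 0 allows.

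The difference between Dup-LdeltaBor and Dup-L covered contacts inside P and inside Q, between P and Q, and between the outer flanks. Loss of the boundary alone, acting as it does without the duplication, is argued against for the contacts inside P and Q. The lowest block fold in Dup-LdeltaBor over Dup-L was compared with the highest in deltaBor over WT, scaled on contacts outside the Dup-L segment. It was 1.15 times as high inside P and 1.05 times inside Q. With the main scale of deltaBor, which these contacts help set, the lower of these ratios was also 1.05. Another effect of that loss within the repeat was not tested. A wrong scaling factor, which would move all blocks alike, is argued against because the lower of the median block folds inside P and Q was 1.26 times the upper end of the central 95% of control block folds. A larger number of duplicated copies per genome in the Dup-LdeltaBor library may account for these and for the outer flanks. Same-bin contacts inside the segment, relative to the median bin outside it, were 1.37 times those of Dup-L. This value is not on the scale of the region folds. The junction signal was 1.94 times as high. For P with Q, block folds fell with separation on the reference (Spearman rho -0.831 across 33 blocks, which are not independent) instead of rising toward the junction. This argues against more junctions alone for the pattern across blocks, not for the size of the rise in most of them. The median fold was 2.39 in the 6 blocks whose Q side lay nearest the lost boundary. In the other blocks it was 1.99, near the junction ratio of 1.94, and 27 of 33 blocks lay above that ratio. Across the same 33 blocks, these folds ranked much as those of deltaBor over WT did (Spearman rho 0.901, blocks not independent). Loss of the boundary, the difference the design names, goes with this pattern. It stays open there, since each genotype has 1 library. Copy number also differs, so the 2.04-fold rise does not estimate the effect of that loss alone.

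The rise of P with Q in Dup-L and Dup-C was also weighed. Copy number alone is argued against, since the lowest P with Q block fold was 1.43 times the highest block fold inside P or Q in Dup-L and 1.67 times in Dup-C. Head-to-tail adjacency with a decay like that inside the WT telomeric-side domain is argued against in Dup-L as the whole source of the excess. Against the domain taken to the next minimum, the log-log slope of the excess was 0.610 (0.592 to 0.624 leaving out 1 separation at a time), or 0.415 over WT without copy number. Against the 1260 kb domain the slopes were 0.645 and 0.502. Pairs farthest apart through the junction are those closest across the boundary, so added contacts there would flatten the slope. The decay of the junction contacts by themselves was therefore not measured. In Dup-C the slopes were 0.966 and 0.765 against the longer domain, on either side of the bound set beforehand at 0.8, and 1.01 and 0.833 against the shorter, so adjacency of this kind cannot be told apart from another decay there. A domain formed by the repeat, the biological explanation the design names, stays open and was not tested separately from adjacency.

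The contacts left in the lost bin of Dup-LdeltaBor were 3.79% of those in Dup-L before any scaling. Reads of other places mapped to this bin are argued against by the deltaBor library, which held 0 contacts there. Their distribution over 100 kb windows followed that of the same bin in Dup-L (Pearson r = 0.951 across windows, which are not independent) more closely than that of any of the 40 other bins within 200 kb (0.749 to 0.937), consistent with chromosomes that kept the bin or with reads of another library. These alternatives were not separated, and no biological explanation was tested.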

How the results depend on the processing

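Results with the domain extended to the next minimum, with the lost bin left out of the WT share, with more bins left out beside the lost bin, and of the piece duplicated only in Dup-C were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library and the labels give no shared replicate numbers. Contacts of gene starts were not run for want of an annotation on mm9. Of the alternatives for the main results, 58 stayed within the counting interval of the main value, 75 lay outside it without turning, many by little, and 7 turned to the other side of 1, or of 0 for log2 values (lengths of segments, which have no interval, were held to a factor of 1.5); among the other values these counts were 49, 64 and 25. Turning was counted only where the main interval excluded 1 or 0, so values that crossed 1 for the rest of the domain in Dup-S with the other domain (0.978, 0.917 and 0.992) and for P with the centromeric-side rest in Dup-LdeltaBor are not among those that turned. Unless said, the cause was not tested.

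KR balancing gives all bins equal sums and so removes copy number by construction, along with any other change in a bin's total contacts. A gain of a bin in 1 region then lowers its values in others. Values that turned below 1 are therefore not by themselves losses of contacts. With it, contacts between domains were 1.61 in deltaBor. Dup-S gave 1.06 for the segment with itself, 0.995 with the rest of its domain and 1.05 with the other domain. P with Q gave 2.21 in Dup-L, 2.36 in Dup-C and 1.37 in Dup-LdeltaBor. P with the telomeric-side rest and Q with the centromeric-side rest gave 0.920 and 0.973 in Dup-L, 0.840 and 0.872 in Dup-C, and 1.47 and 1.31 in Dup-LdeltaBor. Junction folds were 1.69 in Dup-S, 5.01 in Dup-L, 9.14 in Dup-C and 6.41 in Dup-LdeltaBor. The WT share between domains was 11.5%, and 11.7% in raw counts with the lost bin left out. Boundary minus centromeric-side end was -0.47 in WT, 0.56 in deltaBor, -0.51 in Dup-S, 0.25 in Dup-L, 0.43 in Dup-C and 0.84 in Dup-LdeltaBor. Folds that turned below 1 were, in deltaBor, 0.971 and 0.988 within the domains, 0.989 for P with P and 0.986 for Q with Q. P with P, Q with Q and P with the centromeric-side rest turned to 0.884, 0.956 and 0.804 in Dup-L and to 0.916, 0.958 and 0.778 in Dup-C. In Dup-LdeltaBor P with P turned to 0.896 and Q with Q to 0.961, and in Dup-L the piece duplicated only in Dup-C turned to 0.986 with Q.

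Scaling to the library total, which contains the duplicated contacts, gave 1.48 between domains in deltaBor. Dup-S gave 1.75, 1.21 and 1.32 for the segment with itself, the rest of its domain and the other domain. P with Q gave 3.78 in Dup-L, 3.93 in Dup-C and 1.77 in Dup-LdeltaBor. The same flank folds were 1.05 and 1.08 in Dup-L, 0.841 and 0.833 in Dup-C, and 1.49 and 1.35 in Dup-LdeltaBor. Junction folds were 2.83, 8.74, 13.9 and 14.7 in Dup-S, Dup-L, Dup-C and Dup-LdeltaBor. Also below 1 were, in deltaBor, 0.923 and 0.903 within the domains, 0.960 for P with P and 0.903 for Q with Q, and P with the centromeric-side rest at 0.946 in Dup-L and 0.794 in Dup-C.

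Leaving out contacts under 10 bins apart gave 1.67 between domains in deltaBor, 2.23 for the Dup-S segment with itself and 1.43 with the other domain. P with Q became 4.74 in Dup-L and 5.96 in Dup-C, and Q with the centromeric-side rest 1.33 and 1.24. In deltaBor the telomeric-side domain turned to 0.992 and Q with Q to 0.987.

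With distances weighted equally, contacts between domains were 1.67 in deltaBor, and the Dup-S segment gave 2.49 with itself and 1.31 with the rest of its domain. P with Q was 5.00 in Dup-L, 6.34 in Dup-C and 2.08 in Dup-LdeltaBor, where P with the telomeric-side rest was 1.67. Junction folds were 3.21 in Dup-S and 22.6 in Dup-C. In deltaBor 0.934 and 0.891 within the domains, 0.992 for P with P and 0.885 for Q with Q lay below 1.

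Domains from a 200 kb diamond gave 1.76 between domains in deltaBor, 1.41 for the Dup-S segment with the other domain, and 1.36 and 1.87 for Q with the centromeric-side rest in Dup-L and Dup-LdeltaBor. The WT share between domains was 7.69%. Scores from a 200 kb diamond were also taken at the boundary and at the centromeric-side end that the 500 kb diamond had set. Boundary minus that end was -0.53 in WT, 0.74 in deltaBor, -0.47 in Dup-S, 1.27 in Dup-L, 1.63 in Dup-C and 2.48 in Dup-LdeltaBor. Extending the telomeric-side domain gave 1.60 between domains in deltaBor, 1.35 for the Dup-S segment with the rest of its domain and 1.61 for P with the telomeric-side rest in Dup-LdeltaBor. Leaving out 2 more bins on each side of the lost bin gave 2.05 for P with Q in Dup-LdeltaBor. Junction corners of 200 kb gave 2.28, 7.71, 13.4 and 15.1, and corners of 50 kb 4.13, 14.4, 34.1 and 27.8, in Dup-S, Dup-L, Dup-C and Dup-LdeltaBor. A running median gave 30 kb for the deltaBor loss. Dup-C had the fewest contacts, 4144258, and 1636 of its blocks had enough counts to be ranked, against 1653 in each other comparison.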

Other observations

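The comparison in this part was chosen after the segments were seen.

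The 190 kb duplicated in Dup-C and not in Dup-L, 110770001 to 110960000, set the largest duplication apart. In Dup-C this piece contacted Q 8.20 times as often as in WT (8.10 to 8.31), with itself 2.23 times and with the shared part of P 2.22 times (2.19 to 2.24). In Dup-L, where the piece lies just outside the duplication, its fold with Q was 1.38 (1.36 to 1.40), and in Dup-S it was 1.19 (1.17 to 1.21). The fold with Q was 1.66 (1.64 to 1.69) in deltaBor and 2.25 (2.22 to 2.28) in Dup-LdeltaBor. Among the mutants only deltaBor carries no extra copy of Q or of a part of it, so the other raw folds with Q contain copy number. Of the piece's contacts within both domains, 11.8% joined Q in WT, 12.9% in Dup-S, 14.9% in Dup-L, 17.6% in deltaBor, 22.6% in Dup-LdeltaBor and 39.8% in Dup-C. With KR-normalised values its fold with Q was 3.40 in Dup-C, 1.61 in deltaBor, 1.36 in Dup-LdeltaBor, 1.01 in Dup-S and 0.986 in Dup-L, which places deltaBor above Dup-LdeltaBor and Dup-L below 1.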
